A study of Mus musculus with 768 samples.

How the data were processed

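Tomato-positive cells of the sympatho-adrenal anlage of Wnt1-Cre/R26Tomato mouse embryos were sorted singly into plates of 384 wells, 1 plate per age (E12.5 and E13.5), and their polyadenylated RNA was sequenced by the Smart-seq2 protocol, which covers whole transcripts and carries no molecular identifiers. The deposited files hold raw read counts per gene symbol, with 1 column per well. According to the submitters' processing notes, reads were aligned to the mouse genome build mm9 with TopHat2 and counted with HTSeq. Their versions and the gene annotation are not given in the sources used here. All values were whole numbers, 0 of the 768 columns were left without a sample, and 0 pairs of wells had identical values. The annotation available for this work belongs to another genome build, so no gene positions are given.

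The files held 23420 gene symbols. A well was kept as a cell with at least 50000 reads on genes and at least 2000 genes with a read, which kept 380 and 371 wells. All 4 wells lost at E12.5 and all 13 lost at E13.5 had fewer than 50000 reads, and 9 of the latter also had fewer than 2000 genes. Kept wells held 102746774 reads in all at E12.5 and 91674052 at E13.5. The ribosomal RNA gene Rn45s took a median of 2.93% and 2.87% of the reads of a well and at most 24.4% in 1 E13.5 well. Thinned to 100000 reads (seed 5), 369 and 362 cells had medians of 6844 and 6229 genes.

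Before the data were examined, 339 genes were set out in 11 marker lists for cell types and 18 programme lists, and all 339 were found. The programme lists covered catecholamine synthesis and storage, dense-core granules, sympathoadrenal and glial or crest transcription factors, Schwann lineage, mature myelin, Notch, neuronal cytoskeleton, growth factor receptors, postsynaptic genes, hypoxia, G1S and G2M phases, cell cycle inhibitors with D cyclins, imprinted genes, matrix and adhesion, Hox genes, and stress and immediate early genes. The marker lists covered SCPs, bridge cells, chromaffin cells, sympathoblasts, mesenchyme, endothelium, erythroid cells, adrenal cortex, immune cells, sensory neurons and melanocytes.

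Cells of each age were clustered on their own, on log2(CPM+1) of the 2000 most variable genes (20 bins of mean level, genes read in at least 10 cells) of a random set of the expressed genes (1 gene in 2, seed 11) without any listed gene. This left 11696 genes to choose from. From 20 principal components (scikit-learn), a graph of 15 neighbours was partitioned by the Leiden method at resolution 1 (seed 1). A cluster took the name of the class with the highest marker score, scaled over clusters, if it led the next class by at least 0.1 and no other class had more markers among the 10 leading genes of the cluster. Other clusters were named after the adjoining pair of classes. The margin of 0.1 was set after the clusters were seen. Levels per class are summed reads as CPM with exact Poisson 95% intervals, where a gene without reads is given the limit of 3 counts. That limit ran from 0.101 to 0.514 CPM over the 4 classes and 2 ages, which have summed reads of 5839029 to 29592930.

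Programme lists were compared between classes at each age and between ages within each class of at least 20 cells. A gene counted as measured with at least 5 CPM in either group. Folds were taken with a pseudocount of 1 CPM, which exceeds the limit of 3 counts in every class. Each list is given by the number of measured members at least 2-fold higher or lower, the median log2 fold, and the percentile of that median among 10000 random lists of equal size and like expression. Cells of 1 plate are not replicates, so no p-value was computed for a difference between classes or ages. Shares of cells are given with exact Clopper-Pearson 95% intervals. A cell counted as carrying mitosis transcripts with at least 5 of the 20 G2M genes after thinning to 100000 reads, and as carrying a pair of genes with at least 2 reads of each. A cell was called male or female with at least 5 reads of the Y-linked genes or of Xist alone.

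The genes named follow a rule set beforehand. In each list they are the members of largest fold, here by the smaller fold of the 2 ages. Outside the lists and the clustering genes they are up to 5 genes per direction at least 4-fold different in the same direction at both ages, with at least 20 CPM and a read in at least 50% of cells of the higher class at both ages, by the smaller fold of the 2 ages. For bridge-like cells they are up to 8 genes at least 2-fold above each other class at both ages, and all listed genes that meet the same limits. Between ages they are the 5 highest and 5 lowest genes by fold with at least 50 CPM and a read in 50% of cells at the higher age. Unnamed predicted genes were passed over. Other list members named, among them Mki67, Ccnd1, Pnmt, Penk, Dbh, Isl1, Sox10 and Igf2 where they are not the largest, were picked after their values were seen, as widely known members. Results that need certain listed genes are not reported here.

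Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for scaling factors (TMM) in 1 alternative only. The steps were tested on simulated data made from the same classes with 200 changed genes. The simulated spread between cells was that of E12.5 chromaffin-like cells for every class and age. Classes with a wider spread can pass 2-fold more often. Unchanged genes passed 2-fold in 2.14 to 9.48% of cases. True 2-fold differences were found in 35.8 to 55.2%, 4-fold in 92.5 to 100% and 8-fold in 97.0 to 100%. Separately, cells were drawn from the summed profile of each of the 4 named classes, without the boundary groups. Of these cells 100% received the right class name, which bears on well separated classes only and not on cells between them.

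Alternatives tried beforehand changed the limit on genes per well, the random set of genes, the listed genes in clustering, the resolution, the seed, clustering of both ages together, the wells with most genes, the part of the plate, the scaling, the pseudocount, the limit on levels, and mean or median over cells in place of summed reads. Others were added later, as the closing section states. No coordinates, splicing or trajectory was analysed, the latter because an order of cells in time cannot be read from 2 samples.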

Results

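Messenger RNA of single cells was measured in mouse embryos on 2 successive days of gestation, called E12.5 and E13.5 after the days since conception. The cells came from the sympatho-adrenal anlage, the tissue from which the adrenal medulla and nearby sympathetic ganglia form. The embryos carried Wnt1-Cre and the R26 Tomato reporter, which marks descendants of the neural crest, and Tomato-positive cells were sorted singly into 384 wells per age. Of the 384 wells of each age, 98.96% were kept as cells at E12.5 (4 left out, exact 95% interval 97.4 to 99.7) and 96.6% at E13.5 (13 left out, 94.3 to 98.2). Kept wells held 66289 to 390317 reads on genes at E12.5 (median 280642) and 54463 to 344318 at E13.5 (median 259683), with medians of 7360.5 and 6635 genes per cell. The labels name no animal, so each age was 1 sample without replicates. No difference was tested, and a difference between ages can be age, litter or plate. Intervals cover counting error only. They leave out the spread between animals, and those of levels also the spread between cells, whose reads were summed. Because reads carry no molecular identifiers, copies of the same molecule are not told apart, so intervals of levels are too narrow even for counting.

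The first question was which cell types the neural crest lineage held in this tissue at each age. Schwann cell precursors (SCPs) are glial cells on developing nerves, chromaffin cells are the hormone-secreting cells of the adrenal medulla, and sympathoblasts are immature sympathetic neurons. Cells fell into 4 classes at both ages. They were named SCP-like, bridge-like, chromaffin-like and sympathoblast-like after marker genes fixed before the data were examined, with the name bridge used for cells marked by genes such as Htr3a, Thbd, Dll3, Tlx2 and Asb4. Levels are given as the summed reads of a class scaled to a total of 1000000 (CPM). SCP-like cells had Sox10, a transcription factor of glia and neural crest, at 1001 CPM (95% interval 977 to 1025) at E12.5. Bridge-like cells had Htr3a, a serotonin-gated ion channel subunit, at 291.1 CPM (95% interval 284.7 to 297.6), with 1.06 CPM in SCP-like and 14.8 in chromaffin-like cells. Chromaffin-like cells had the granule protein chromogranin A, Chga, at 2620.4 CPM (95% interval 2601 to 2640.0). Sympathoblast-like cells had the neuropeptide gene Cartpt at 698 CPM (95% interval 682 to 715) and the neuronal filament gene Prph at 543 CPM.

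Shares of SCP-like, bridge-like and sympathoblast-like cells differed most between the ages. SCP-like cells made up 6.58% of kept cells at E12.5 (25 cells, 4.30 to 9.56) and 21.8% at E13.5 (81 cells, 17.7 to 26.4). Bridge-like cells made up 26.1% (99 cells, 21.7 to 30.8) and 6.74% (25 cells, 4.41 to 9.79). Sympathoblast-like cells made up 9.47% (36 cells, 6.72 to 12.9) and 32.3% (120 cells, 27.6 to 37.4). Chromaffin-like cells made up 25.5% (97 cells, 21.2 to 30.2) and 23.2% (86 cells, 18.98 to 27.8). Groups with markers of adjoining classes were kept apart. An SCP/bridge group held 13.9% of cells at E12.5 (53 cells, 10.6 to 17.8) and 0% at E13.5 (upper bound 0.989%). A bridge/chromaffin group held 18.4% (70 cells, 14.7 to 22.7) and 15.9% (59 cells, 12.3 to 20.03). This group depended on the grouping. At E13.5 it held 0 cells with another seed, at resolution 0.5 or 2, and with both ages clustered together. It was also absent there after thinning, without the wells with most genes, and when other or all expressed genes were used for clustering. At E12.5 it was absent at resolution 2 and with both ages together. At E12.5 the classes came from clusters 9 (SCP-like), 4, 6 and 8 (bridge-like), 2 and 7 (chromaffin-like) and 5 (sympathoblast-like). At E13.5 they came from clusters 1, 7, 4 and 6, and 3, 5 and 8 in that order. Of 15 ways of choosing wells or grouping cells, 4 were parts of the plates or of the sexes under the same grouping and 1 had the same cells and classes. The SCP-like and sympathoblast-like shares were higher at E13.5 and the bridge-like share lower in all 15. The chromaffin-like share was higher at E13.5 in 11 and lower in 4. Those 4 were the reported grouping, the way with the same cells and classes, rows A to H and female cells. Every way that changed the grouping gave a higher chromaffin-like share at E13.5, some with overlapping intervals. With another seed it was 16.8% at E12.5 and 32.3% at E13.5. The SCP-like difference depended on the SCP/bridge group, and at resolution 0.5 all 78 cells of these groups at E12.5 were named SCP/bridge. Counted together, the groups made up 20.5% of cells at E12.5 (16.6 to 24.9) and 21.8% at E13.5, and the intervals of the ages overlapped in 11 of the 15 ways and lay apart in the 4 that had no SCP/bridge cells at E12.5. Among female cells the joined share was lower at E13.5 (30.8% and 17.2%), and in rows I to P it was 24.6% at both ages. The sizes of the bridge-like class did depend on the wells chosen and the grouping. Without the parts of the plates or sexes they ran from 26.1 to 48.8% of cells at E12.5 and 6.50 to 21.8% at E13.5. The lowest shares of all came from such parts, 20.9% in rows I to P at E12.5 and 5.96% of female cells at E13.5. Clustering on the unlisted genes left out of the grouping put 77.9% and 83.02% of cells in the same class at E12.5 and E13.5.

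**Figure D1:**
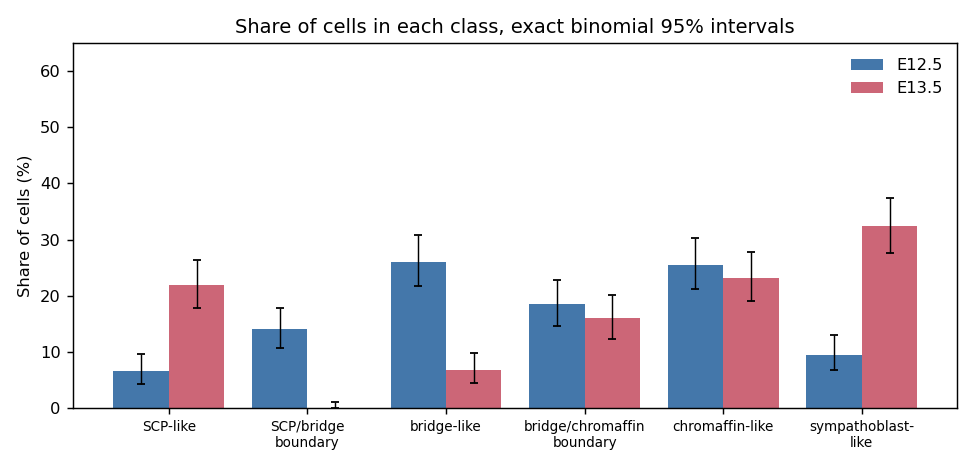
Share of kept cells in each class (percent, vertical axis) at E12.5 and E13.5, with bars as the share and lines as the exact binomial 95% interval. The sympathoblast-like share was 9.47% at E12.5 and 32.3% at E13.5, and the bridge-like share 26.1% and 6.74%.

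The sympathoblast-like share also differed between male and female cells at E13.5. Xist, the RNA of the inactive X chromosome, marked 28.2% of cells as female at E12.5 and 40.7% at E13.5, and Y-linked genes marked 68.4% and 52.3% as male. Sympathoblast-like cells were 54.3% of female (46.01 to 62.4) and 14.4% of male cells (9.81 to 20.2) at E13.5, against 11.2% (5.93 to 18.8) and 8.46% (5.38 to 12.53) at E12.5. Bridge-like cells were 21.5% of female and 28.5% of male cells at E12.5 and 5.96% and 7.22% at E13.5. SCP-like cells were 4.62% of male cells at E12.5 and 25.3% at E13.5, while the shares among female cells, 11.2% and 17.2%, had overlapping intervals. Chromaffin-like cells were 16.8% of female and 28.8% of male cells at E12.5 and 12.6% and 32.5% at E13.5. Of sympathoblast-like cells of known sex, 74.5% were female at E13.5 (65.4 to 82.4), against 23.2% of chromaffin-like cells (14.6 to 33.8).

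**Figure D2:**
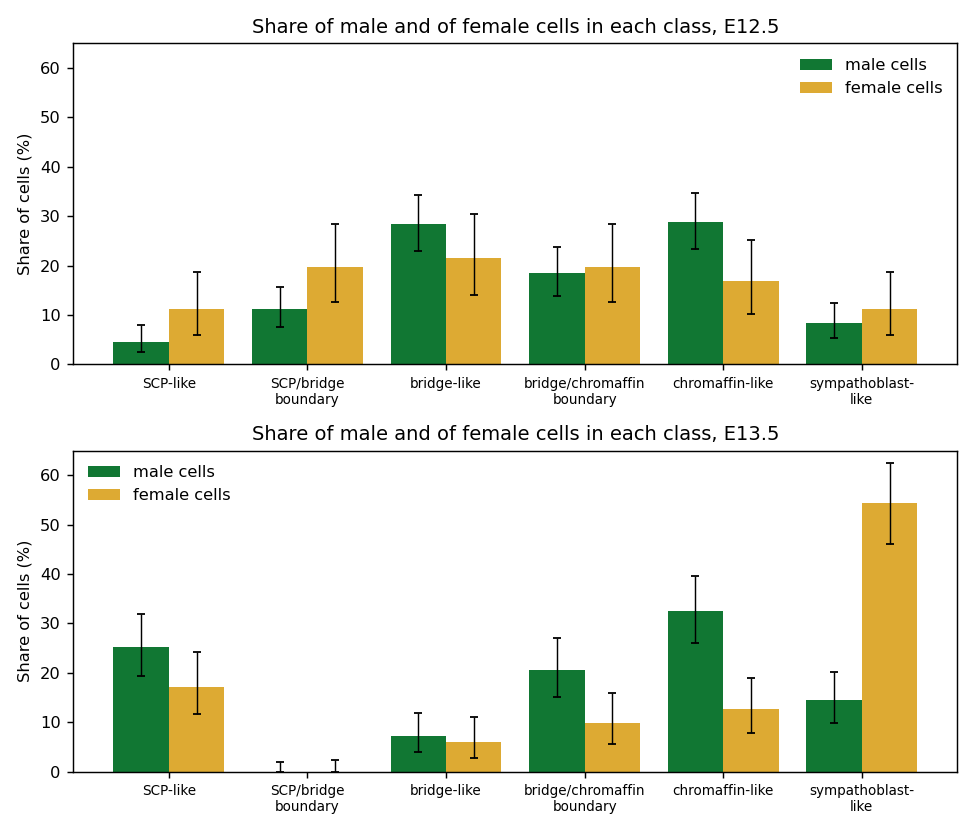
Share of male and of female cells in each class (percent, vertical axis) in a panel per age, with bars as the share and lines as the exact binomial 95% interval. At E13.5 the sympathoblast-like share was 54.3% of female and 14.4% of male cells.

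Bridge-like cells were compared with SCP-like cells to ask which genes set cells between the glial and the chromaffin state apart from the glial precursors. Bridge-like cells had lower levels of most Schwann lineage genes and higher levels of most transcription factors of the sympathetic and chromaffin lineages at both ages. Gjc3, a gap junction gene of glia, was nearly confined to SCP-like cells. It stood there at 62.6 CPM at E12.5 and 114.4 CPM at E13.5, against 0.0369 and 0 CPM in bridge-like cells, where 0 reads allow up to 0.111 CPM at E12.5 and 0.514 CPM at E13.5. Where 2 pairs of levels are given, E12.5 stands before E13.5. Isl1, a transcription factor of neurons, stood at 509.8 against 1.21 CPM at E12.5 and 183.4 against 2.58 CPM at E13.5, and Phox2a, a factor that switches on noradrenaline synthesis, at 203.5 against 1.81 and 98.99 against 2.33 CPM. Sox10 was present in both classes, at the lower level in bridge-like cells (63.4 against 1001 and 200.7 against 1205 CPM).

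Of the glial and crest factors, 6 of 13 measured at both ages were at least 2-fold lower in bridge-like cells at both, with median log2 folds of -2.17 at E12.5 and -1.41 at E13.5. Foxd3 (2.18 against 61.7 and 4.11 against 93.4 CPM) and Sox10 differed most. Of the Schwann lineage genes, 13 of 19 were lower at both ages (medians -3.03 and -2.47). Among them were Gjc3, the calcium-binding protein gene S100b (0.0369 against 51.6 and 7.19 against 137.99 CPM) and the endothelin receptor Ednrb (64.4 against 3622 and 379.2 against 5558 CPM). Matrix and adhesion genes were lower too, 14 of 18 at both ages (medians -3.40 and -2.37). The largest differences were those of the integrin Itga4 (8.27 against 695 and 21.2 against 497 CPM) and the collagens Col4a1 (16.7 against 244.7 and 64.4 against 613 CPM) and Col4a2. Of the sympathoadrenal factors, 10 of 13 were at least 2-fold higher at both ages (medians 3.84 and 3.31). Isl1, Phox2a, Insm1 (302.99 against 15.4 and 247.1 against 4.41 CPM) and Tlx2 (499 against 4.67 and 559.5 against 29.6 CPM) stood in front. Neuronal cytoskeleton and RNA-binding genes followed with 14 of 17 (medians 2.25 and 2.31). Examples were Elavl3 (153.6 against 0.754 and 116.6 against 0.0496 CPM), the tubulin Tubb3 (1576 against 23.1 and 767 against 9.86 CPM) and the neurofilament Nefm (1536 against 26.2 and 936 against 19.5 CPM). Genes of the receiving side of synapses counted 9 of 11 (medians 4.12 and 3.64), led by Htr3a and the nicotinic receptor subunit Chrna3 (183.9 against 0.452 and 88.5 against 0.0496 CPM). Hox genes, which mark position along the body axis, were higher in 7 of 22 (medians 0.86 and 1.41), led by Hoxb6 (43.98 against 7.54 and 63.2 against 6.99 CPM), Hoxa5 and Hoxa9.

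Notch genes were divided. The ligand genes Dll3 (458 against 2.71 and 462 against 2.28 CPM) and Dll1 (128.6 against 2.41 and 111.7 against 0.991 CPM), the glycosyltransferase Mfng (350.6 against 1.21 and 314.8 against 3.82 CPM) and Hes6 were higher in bridge-like cells at both ages. Jag1 (1.85 against 150.8 and 5.65 against 217.7 CPM), Heyl, Notch2 and Notch3 were lower, so that the medians of 0.10 and -0.93 joined opposite members. Receptors of growth factors split as well, with medians of -2.73 and -0.61. Ret (162.7 against 1.96 and 302.96 against 4.51 CPM), Sstr2 and Kit were higher, and 7 of 13 were lower, led by Gfra3 (19.6 against 332.5 and 3.77 against 556 CPM), Gfra2 and Ednrb. Dense-core granule genes were higher in 16 of 20 measured members at E12.5 and 8 of 15 at E13.5 (medians 2.56 and 1.38). Cpe, which trims peptide hormones, stood at 92.5 against 0.151 and 127.6 against 3.87 CPM and Scg3 at 215.9 against 0.603 and 157.4 against 5.50 CPM. Genes of catecholamine synthesis and storage were higher in 7 of 10 at E12.5 and 3 of 9 at E13.5 (medians 2.62 and 0.47). The vesicle transporter Slc18a1 (162.02 against 0.754 and 30.5 against 0.793 CPM) and Cyb561 (247.8 against 1.06 and 46.9 against 2.53 CPM) were higher at both. The mature myelin list gave no median at E12.5, where too few of its genes were measured, and at E13.5 all 3 measured members were lower (-1.70), with Prx lower at both ages.

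The cell cycle inhibitor gene Cdkn1c was the most abundant listed gene that set bridge-like cells apart, at 9651 CPM (95% interval 9614 to 9688) against 2391 CPM in SCP-like cells at E12.5 and 10129 CPM (95% interval 10048 to 10211) against 1366 at E13.5. Among inhibitor and cyclin D genes, Btg2 (157.1 against 23.1 and 265.6 against 9.37 CPM) and Btg1 were also higher at both ages (list medians 1.44 and 0.87). Imprinted genes were higher in 6 of 16 (medians 0.67 and 1.03). They were led by Dlk1 (183.4 against 2.26 and 64.4 against 8.43 CPM) and the growth factor gene Igf2 (225.2 against 39.95 and 333.1 against 62.6 CPM), with Mest lower. Hypoxia genes had 3 of 11 members higher, Ndufa4l2 (82.3 against 2.11 and 44.01 against 3.52 CPM), Vegfa and Bnip3, while the list medians were 0.26 at both ages. G2M genes, used in mitosis, were at least 2-fold higher in bridge-like cells in 12 of 20 at E12.5 and lower in 4 of 20 at E13.5 (medians 1.39 and -0.35). The E12.5 class included cluster 8 (25 cells), whose leading genes held mitosis genes such as Kif23 and Aspm. No such gene led the E13.5 class, so the change between ages depends in part on which clusters were joined. G1S genes, used in DNA replication, had medians of -0.02 and 0.24. The stress and immediate early list had medians of 0.51 and 0.77, with Dusp1 (91.3 against 32.9 and 197.1 against 25.6 CPM) and Btg2 higher at both ages.

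Genes that took no part in the grouping and stood in no list gave further differences of at least 4-fold at both ages. Higher in bridge-like cells were the neurexophilin Nxph4 (149.8 against 0.302 and 103.3 against 0.149 CPM), the retinol receptor Stra6 (346.4 against 3.02 and 170.7 against 2.87 CPM) and Cadps2, a factor of vesicle release (99.7 against 1.51 and 70.4 against 0.694 CPM). The hormone gene secretin, Sct (73.3 against 0 and 75.2 against 0.942 CPM), and the matrix protein gene Mfap4 (216.4 against 1.96 and 264.1 against 6.59 CPM) were higher as well. Lower were the protease Prss12 (1.11 against 531 and 2.74 against 569 CPM), the collagen Col14a1 (0.332 against 173.99 and 0.856 against 274.3 CPM) and Egfl8 (1.88 against 182.3 and 0.514 against 605 CPM), followed by Afap1l2 and the protease Adamts5. Some genes were higher in bridge-like cells than in each of the other 3 classes at both ages. They are given by the smallest of these folds, with 1 CPM added to each level. Outside the lists they were Sct (10.5-fold), the growth arrest gene Gadd45g (10.2), the creatine kinase Ckb (7.15), Cadps2 (3.76), Pik3r3 (2.71), the transcription factor Tbx3 (2.48), Stra6 (2.29) and Fam110a (2.28). Within the lists, Htr3a led (12.52-fold), ahead of Dll1 (7.60), Hes6 (4.55), Cdkn1c (4.04), Btg2 (3.59), Hoxd3 (2.80), Mfng (2.48) and Dll3 (2.30).

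The programme lists hold some of the marker genes that named the classes, such as Sox10 and Foxd3 among the glial factors, so the direction of those members follows in part from the naming. Without such genes the medians of bridge-like over SCP-like cells were -1.83 and -0.94 for glial factors and -2.10 and -1.90 for Schwann lineage genes. They were 3.51 and 2.31 for sympathoadrenal factors and 2.38 and 2.33 for neuronal genes. By the marker lists themselves, the SCP list stood at -4.06 and -3.14, the bridge list at 6.39 and 5.41, the chromaffin list at 5.10 and 1.79 and the sympathoblast list at 2.46 and 3.63. Markers of mesenchyme differed between the ages, with a median of -1.16 at E12.5 and 0.78 at E13.5. The collagen genes Col1a2 and Col1a1 stood at 404 and 299.02 CPM in E13.5 bridge-like cells, with Col1a1 read in 16% of them.

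Chromaffin-like cells were compared with SCP-like cells to ask what separates the endocrine cells from the glial precursors of the same lineage. Most genes for making, packing and releasing catecholamines were higher in chromaffin-like cells. Th, the rate-limiting enzyme of catecholamine synthesis, stood at 3428 CPM (95% interval 3406 to 3450.2) against 6.33 CPM at E12.5 and 4068 CPM (95% interval 4042 to 4095) against 20.3 CPM at E13.5. Dbh, which makes noradrenaline, stood at 4175 against 15.98 and 6295 against 21.1 CPM. Chromogranin B, Chgb, a main protein of the secretory granules, stood at 7872 against 3.92 and 17099.8 against 28.1 CPM. Ednrb (14.5 against 3622 and 25.04 against 5558 CPM) and the neuregulin receptor Erbb3 (1.32 against 249.8 and 0.504 against 336.04 CPM), through which glial precursors receive growth signals, were lower, as were nearly all genes of DNA replication and mitosis.

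Catecholamine genes were at least 2-fold higher at both ages in 8 of 11 measured members (medians 6.18 and 6.62). Slc18a1 (1021 against 0.754 and 1489.6 against 0.793 CPM), Cyb561 (1935 against 1.06 and 1814 against 2.53 CPM), Dbh and Th stood in front. Granule genes were higher in 18 of 20 (medians 4.91 and 4.97). Among them were Chgb, Chga (2620.4 against 4.82 and 5557 against 8.72 CPM), Rab3c and the release protein Snap25 (593 against 6.03 and 1304 against 7.04 CPM). Pnmt, which turns noradrenaline into adrenaline, had 0 reads in E12.5 chromaffin-like cells, which allows up to 0.114 CPM, and 19.99 CPM (95% interval 18.2 to 21.96) at E13.5, from 2.33% of the cells. Penk, the gene of the enkephalin peptides, stood at 298.5 and 238.6 CPM, read in 52.6% and 45.3% of chromaffin-like cells. Sympathoadrenal factors were higher in 10 of 14 (medians 4.66 and 4.60). They were led by Hand1 (294.4 against 1.21 and 437 against 1.98 CPM), Phox2a and Isl1, while Sox4 and Sox11 (65.8 against 150.9 and 45.03 against 103.3 CPM) were lower. Neuronal genes were higher in 17 of 21 (medians 4.005 and 3.59), such as Elavl3, Stmn3 and Mapt. Postsynaptic genes were higher in 9 of 10 (medians 5.30 and 5.01), such as Chrna3 (382.9 against 0.452 and 207.6 against 0.0496 CPM) and Rgs4 (3279 against 1.81 and 4108 against 31.7 CPM). Hypoxia genes were higher in 7 of 13 (medians 1.64 and 1.99). Epas1, the oxygen-sensing factor HIF2alpha (1357 against 3.32 and 1879 against 9.22 CPM), and Ndufa4l2 (581 against 2.11 and 905 against 3.52 CPM) were among the highest. So were the peptide hormone gene Adm (350.8 against 0 and 613 against 2.53 CPM) and the respiratory chain subunit Cox4i2 (70.1 against 1.81 and 111.7 against 0.397 CPM). Imprinted genes were higher in 9 of 16 (medians 1.99 and 2.29), with Mest and Plagl1 lower. Dlk1 (1527 against 2.26 and 2547 against 8.43 CPM), Meg3 (3034 against 55.9 and 6058 against 98.5 CPM) and Rian, which lie in 1 imprinted gene cluster, differed most.

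Lower in chromaffin-like cells at both ages were 11 of 13 glial factors (medians -3.84 and -4.19), led by Zfp488, Foxd3 and Sox10. So were 16 of 19 Schwann lineage genes (medians -4.91 and -5.49). Matrix and adhesion genes were lower in 15 of 18 (medians -5.16 and -5.54), such as Sparc (19.2 against 2469 and 8.12 against 2931 CPM) and the laminin Lama4 (6.43 against 725 and 4.59 against 939.9 CPM). Of growth factor receptors, 9 of 12 were lower (medians -2.94 and -3.39), led by Ednrb, Erbb3 and Erbb2. Ntrk3 (275.9 against 0 and 273.6 against 8.08 CPM) and Ret were higher. G1S genes were lower in 17 of 18 (medians -2.76 and -3.08) and G2M genes in 19 of 20 (medians -3.77 and -4.48). Rrm2, which supplies building blocks of DNA, stood at 5.90 against 173.8 and 5.27 against 93.4 CPM and Bub1 at 0.492 against 85.3 and 0.183 against 95.1 CPM. The cyclins Ccnd1 (193.6 against 888 and 66.5 against 391 CPM), Ccnd2 and Ccnd3 were lower. The inhibitors Cdkn1b and Cdkn2d and Btg1 were higher, in a list with medians of -0.09 and 0.27. Notch genes had 8 of 17 lower, led by Heyl, Jag1 and Notch1, and 5 higher, led by Mfng and Dll3 (medians 0.39 and -2.11). Hox genes had medians of -0.02 and 0.70, with 4 of 20 higher at both ages, Hoxb6 (28.2 against 7.54 and 20.9 against 6.99 CPM), Hoxa5, Hoxa7 and Hoxb8. Hoxb9 (36.9 against 209.3 and 9.17 against 156.97 CPM) and Hoxd9 were lower. The stress list had 0.91 and 2.29, with Fosb, Fos (260.8 against 63.3 and 602 against 69.7 CPM) and Dusp1 higher at both ages. At E13.5 2 of 3 mature myelin genes were lower. Without the genes that named the classes, the medians were 4.73 and 6.08 for catecholamine genes and -3.08 and -5.18 for Schwann lineage genes. The marker lists of the classes stood at -5.58 and -6.36 for SCPs and 2.94 and 2.16 for bridge. They were 9.0002 and 9.01 for chromaffin cells and 3.42 and 3.12 for sympathoblasts.

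Outside lists and grouping, the angiotensin receptor Agtr2 (8138 against 3.62 and 7932 against 12.9 CPM) and Rgs5, which dampens signals of G proteins (448 against 0 and 1170.3 against 2.28 CPM), were highest in chromaffin-like over SCP-like cells. Next came Sez6 (355.01 against 0.302 and 311.8 against 0.149 CPM), the kinase Nrk (2624 against 2.41 and 2239 against 7.68 CPM) and Nxph4. Lower were Afap1l2 (0.0379 against 343.5 and 0.504 against 515 CPM), Prss12 (0.719 against 531 and 0.275 against 569 CPM), Moxd1 (2.76 against 1340.2 and 4.04 against 1399 CPM), Adamts1 and Slitrk6.

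**Figure D3:**
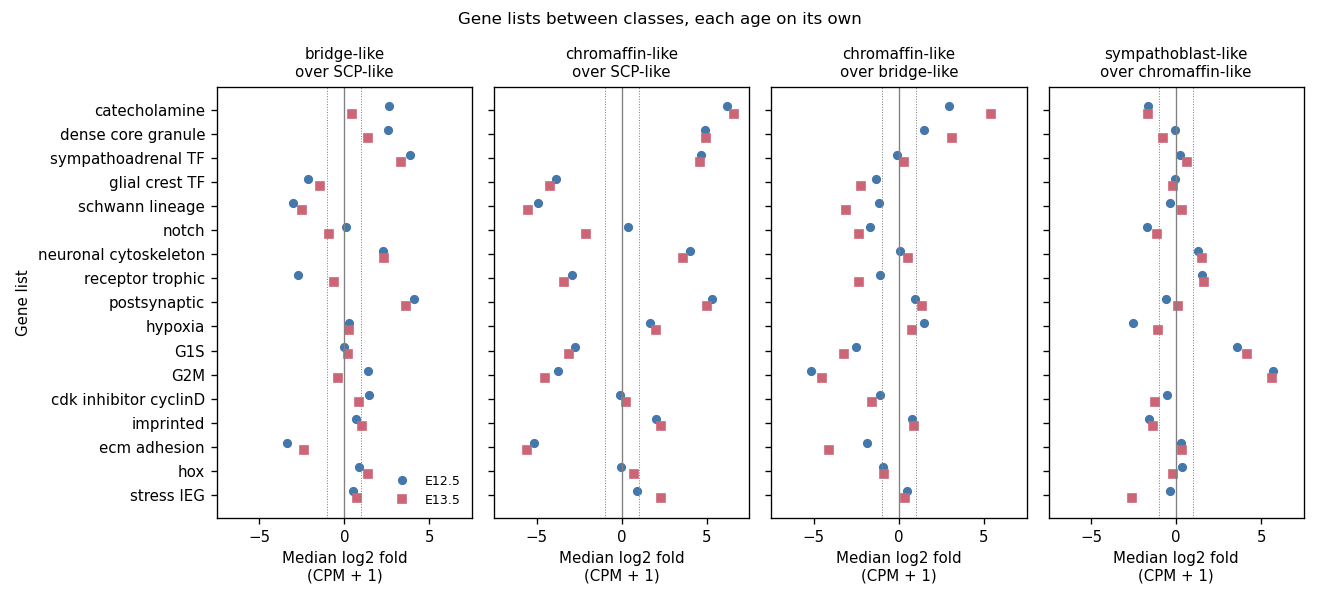
Median log2 fold of each gene list (horizontal axis) for the 4 comparisons of classes, with circles for E12.5, squares for E13.5 and dotted lines at a 2-fold difference. The catecholamine list stood at 6.18 and 6.62 in chromaffin-like over SCP-like cells, and the G2M list at 5.67 and 5.63 in sympathoblast-like over chromaffin-like cells.

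Chromaffin-like cells were compared with bridge-like cells to ask what distinguishes the endocrine cells from the cells that share markers with both sides. Chromaffin-like cells had most catecholamine genes at higher levels, and bridge-like cells had all mitosis genes of the list at higher levels. Gch1, which makes the cofactor of Th, stood at 679 against 5.76 CPM at E12.5 and 1091 against 0.856 CPM at E13.5, and Th itself at 3428 against 51.03 and 4068 against 11.1 CPM. Hand1, a factor of the sympathoadrenal lineage, stood at 294.4 against 7.94 and 437 against 0.514 CPM, with the higher level in chromaffin-like cells. Htr3a (14.8 against 291.1 and 0.0917 against 526 CPM) and Cdkn1c (2241 against 9651 and 754 against 10129 CPM) were lower.

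Catecholamine genes were at least 2-fold higher at both ages in 8 of 11 (medians 2.96 and 5.40), led by Gch1, Th, the transporter Slc18a2 and the noradrenaline transporter Slc6a2. Granule genes were higher in 13 of 21 (medians 1.48 and 3.13), led by Chgb, Ptprn (353.5 against 10.6 and 631 against 0.856 CPM) and Resp18. Hypoxia genes were higher in 5 of 13 (medians 1.45 and 0.74), with Adm (350.8 against 5.10 and 613 against 3.08 CPM) and Epas1 (1357 against 76.4 and 1879 against 8.91 CPM) among them. Of the imprinted genes, 6 of 16 were higher (medians 0.75 and 0.91), led by Dlk1, Meg3 and Rian. Sympathoadrenal factors were divided, with Hand1, Eya1, Tfap2b, Gata2 and Phox2a higher and Sox11 and Sox4 lower (medians -0.11 and 0.29). All 20 G2M genes (medians -5.18 and -4.53) and 17 of 18 G1S genes (medians -2.50 and -3.21) were lower. So were 10 of 15 Notch genes (medians -1.73 and -2.35), led by Notch1 (7.80 against 125.4 and 6.92 against 147.6 CPM), Hes1 and Dll1, with Jag2 and Dll4 higher. Also lower were 7 of 11 glial factors (medians -1.33 and -2.25), 7 of 14 Schwann lineage genes (medians -1.15 and -3.09) and 11 of 15 matrix genes (medians -1.87 and -4.08), led by Fn1 and Sparc. The same held for 7 of 21 Hox genes (medians -0.95 and -0.89), led by Hoxb9 and Hoxc10. Cdkn1c, Btg2, Ccnd2 and Ccnd1 were lower in the inhibitor and cyclin D list (medians -1.10 and -1.61). Of growth factor receptors 6 of 12 were lower, led by Kit and Erbb3, with Ntrk3 and Gfra3 higher. Their medians were -1.14 and -2.37, where the E12.5 value was 0.31 when a median over cells replaced the summed reads. Neuronal genes (medians 0.05 and 0.53) had Mapt and Stmn2 higher and Nefl and Nefm lower. Postsynaptic genes (medians 0.92 and 1.33) had Rgs4 and Cacna1d higher and Htr3b and Htr3a lower. The stress list (medians 0.48 and 0.38) had Junb and Fos higher and Btg2 lower. Mesenchyme markers, higher in bridge-like cells, stood at -2.16 and -4.69. The class markers stood at -2.05 and -3.36 for bridge, 3.88 and 6.38 for chromaffin cells and -1.90 and -3.09 for SCPs. Outside lists and grouping, Galnt6 (299.98 against 1.37 and 529 against 0.171 CPM), Rgs5 (448 against 6.31 and 1170.3 against 1.199 CPM), C2cd4a (176.2 against 2.10 and 208.6 against 0.514 CPM), Ampd3 and Elf4 were higher in chromaffin-like cells. The cyclin Ccna2 (17.6 against 444 and 14.996 against 265.1 CPM), Ckb (101.6 against 1675 and 11.7 against 2459 CPM), Arhgap42 (2.76 against 53.9 and 2.11 against 73.5 CPM), Cdca8 and Fanca were lower.

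Sympathoblast-like cells were compared with chromaffin-like cells to ask how the neuronal and the endocrine branches of the lineage differ. Sympathoblast-like cells carried the transcripts of dividing cells and of growing neurites, and chromaffin-like cells had more of the catecholamine and hypoxia genes. All 20 G2M and all 18 G1S genes were at least 2-fold higher in sympathoblast-like cells at both ages, with medians of 5.67 and 5.63 for G2M and 3.57 and 4.18 for G1S genes. The proliferation marker Mki67 stood at 725 against 9.88 CPM at E12.5 and 659 against 13.53 CPM at E13.5, and the cyclin gene Ccnd1 at 3328 against 193.6 and 2221 against 66.5 CPM. Neuronal genes were higher in 13 of 21 (medians 1.28 and 1.52), led by the microtubule regulator Stmn4 (269.8 against 10.4 and 355.3 against 7.66 CPM), Elavl2 and Prph (543 against 46.8 and 998 against 17.4 CPM).

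Growth factor receptors were higher in 7 of 11 (medians 1.51 and 1.65), with Kit (87.3 against 4.62 and 53.2 against 0.504 CPM), Ret (971 against 177.6 and 584 against 66.95 CPM) and Alk (9.99 against 2.50 and 16.5 against 2.38 CPM), a kinase mutated in some neuroblastomas, in front. Of catecholamine genes 7 of 11 were lower (medians -1.67 and -1.68), led by Th (593 against 3428 and 383.6 against 4068 CPM) and Slc18a2. Dbh was abundant in both classes (2202 against 4175 and 1917 against 6295 CPM), and Slc6a2 was higher in sympathoblast-like cells (42.5 against 15.8 and 154.7 against 69.8 CPM). Granule genes (medians -0.09 and -0.79) had Chgb (320.8 against 7872 and 91.5 against 17099.8 CPM), Chga, Ptprn and Syt7 lower and Pcsk2 and Pam higher. Hypoxia genes were lower in 7 of 14 (medians -2.54 and -1.09), led by Cox4i2 (0.306 against 70.1 and 1.52 against 111.7 CPM) and Ndufa4l2. Egln3, a hydroxylase of the same pathway, was higher (80.3 against 10.7 and 219.2 against 0.963 CPM). Imprinted genes were lower in 9 of 16 (medians -1.59 and -1.34), led by Igf2 (12.3 against 396 and 20.3 against 544 CPM), Peg10 and H19. Sox11, Sox4, Isl1 and Eya1 were higher among the sympathoadrenal factors (medians 0.20 and 0.66). Notch genes were lower in 6 of 11, led by Dll4 and Mfng (medians -1.74 and -1.10, the latter 0.13 with a median over cells). The stress list was lower in 3 of 8 (medians -0.38 and -2.57). Hox genes of the C group, Hoxc8 (45.9 against 5.87 and 57.3 against 4.91 CPM), Hoxc9 and Hoxc10, were higher and Hoxb6, Hoxb7 and Hoxb8 (5.30 against 30.7 and 3.75 against 46.04 CPM) lower (medians 0.32 and -0.20). Other medians were -0.53 and -1.25 for the inhibitor and cyclin D list and -0.61 and 0.09 for postsynaptic genes, with Htr3b higher (46.5 against 0.0757 and 112.97 against 0.0459 CPM) and Rgs4 lower. They were 0.31 and 0.34 for matrix genes, -0.10 and -0.20 for glial factors and -0.38 and 0.33 for Schwann lineage genes. The sympathoblast markers stood at 2.90 and 1.94 and the chromaffin markers at -3.44 and -4.39. Outside lists and grouping, the mitosis genes Pbk (330.3 against 0.114 and 296.7 against 0.734 CPM), Nuf2, Spc25 and Ckap2l and the acetylcholine transporter Slc18a3 (286.2 against 2.50 and 180.7 against 1.38 CPM) were higher in sympathoblast-like cells. C2cd4a (0.510 against 176.2 and 0.439 against 208.6 CPM), Nrk (53.4 against 2624 and 67.1 against 2239 CPM), Dgkk, Fam183b and the adenosine receptor Adora2a (13.3 against 316.9 and 4.09 against 166.7 CPM) were lower.

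The share of cells with mitosis transcripts was then set beside the classes, since it bears on which cells divide. With each cell thinned to 100000 reads, at least 5 of the 20 G2M genes were read in 96.97% of sympathoblast-like cells at E12.5 (84.2 to 99.9) and 86.2% at E13.5 (78.6 to 91.9). Chromaffin-like cells stood at 8.51% (3.75 to 16.1) and 4.71% (1.30 to 11.6). Bridge-like cells stood at 75% (65.1 to 83.3) and 40.0% (21.1 to 61.3), and SCP-like cells at 76% (54.9 to 90.6) and 49.4% (37.9 to 60.9). The boundary groups stood at 86.8% for SCP/bridge cells at E12.5 and at 26.5% and 14.04% for bridge/chromaffin cells at E12.5 and E13.5.

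Cells with transcripts of the glial and the sympathoadrenal programme together were counted to ask whether single cells hold both. Sox10 and Th were read together, with at least 2 reads each of 100000, in 16% of SCP-like, 13.2% of SCP/bridge, 11.5% (5.86 to 19.6) of bridge-like, 27.9% of bridge/chromaffin and 32.98% (23.6 to 43.4) of chromaffin-like cells at E12.5. At E13.5 the shares were 12.7% of SCP-like, 29.8% of bridge/chromaffin and 15.3% (8.40 to 24.7) of chromaffin-like cells, and in bridge-like cells 0 of 25 (upper bound 13.7%). Sympathoblast-like cells, set beforehand as the background, stood at 6.06% (0.743 to 20.2) and 4.31% (1.41 to 9.77). Th alone was read in 90.9% and 80.2% of them, so they give a background for Sox10 but not for Th. SCP-like cells had Sox10 in 100% at both ages, so their share is that of cells with Th. In E12.5 bridge-like cells Sox10 was read in 47.9% and Th in 30.2%. Whether both genes met more often than by chance was not tested. The interval of chromaffin-like cells lay above that of the background at E12.5 and overlapped it at E13.5. That of bridge/chromaffin cells, a group formed only under some groupings, lay above it at E13.5 (18.4 to 43.4) and overlapped it at E12.5 (17.7 to 40.1). That of bridge-like cells overlapped it at both ages. With at least 10 reads of each gene, no interval of these 3 groups lay above the background at either age.

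The ages were compared within each class to ask how each cell type differed between the 2 days. SCP-like cells (cluster 9 at E12.5, cluster 1 at E13.5) had higher levels of Schwann cell maturation genes at E13.5. Mbp, a main protein of myelin, stood at 118.1 against 13.3 CPM, Pmp22 at 146.7 against 19.6 CPM, Mal at 52.8 against 3.62 CPM and Pou3f1, a factor that prepares Schwann cells for myelination, at 11.003 against 0 CPM. Schwann lineage genes were at least 2-fold higher in 8 of 20 (median log2 fold 0.63) and mature myelin genes in 2 of 3 (3.06). The highest folds were those of Mmd2 (206.1 against 6.78 CPM) and the matrilin Matn2 (441 against 31.2 CPM). Mmd2 also stood at 62.4 CPM in SCP/bridge cells at E12.5, so its fold depends on how that group is counted. Olfml2a (150.9 against 17.3 CPM) and Slco3a1 (63.04 against 7.69 CPM) were also higher. Cwc22 (28.7 against 198.7 CPM), Armc6 (11.1 against 51.1 CPM), Kif5c (14.3 against 62.4 CPM), Odc1 (53.2 against 221.3 CPM) and Bcat1 (29.1 against 116.4 CPM) were lower. G1S genes had a median of -0.71 and neuronal genes -0.54. The G2M median was 0.89, with 9 of 20 genes at least 2-fold higher at E13.5, although the share of SCP-like cells with mitosis transcripts was 76% at E12.5 and 49.4% at E13.5. The same median was -2.16 with a median over cells and -0.21 among female cells. Melanocyte markers stood higher in the same class, with Pmel at 172.1 CPM in 11.1% and Dct at 162.2 CPM in 4.94% of E13.5 SCP-like cells. The remaining lists of SCP-like cells had medians of 0.38 (catecholamine), 0.73 (granule), -0.54 (sympathoadrenal factors), 0.46 (glial factors), 0.47 (Notch) and 0.35 (matrix). They were 0.43 for growth factor receptors, -0.48 for hypoxia, -0.40 for stress and -0.25 for inhibitor and cyclin D genes. Postsynaptic, Hox and imprinted genes stood at 0.13, -0.10 and -0.07.

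Chromaffin-like cells (clusters 2 and 7, then 4 and 6) had more of the secretory granule transcripts at E13.5. Granule genes were at least 2-fold higher in 12 of 21 (median 1.12), with Scg2 at 165.8 against 27.4 CPM, Chgb at 17099.8 against 7872 CPM and Chga at 5557 against 2620.4 CPM. Catecholamine genes were higher in 3 of 12, Pnmt, Slc6a2 (69.8 against 15.8 CPM) and Qdpr (median 0.40), and stress genes in 5 of 9 (median 1.15), led by Egr1. Bridge markers were lower in 4 of 5 (median -1.16), among them Dll3 (51.96 against 198.3 CPM) and Htr3a (0.0917 against 14.8 CPM). G1S genes had a median of -0.75, neuronal genes -0.42 and Hox genes 0.43. The highest folds were those of Gpr179 (165.6 against 5.45 CPM), Galnt14 (137.8 against 8.33 CPM), Dgkb (68.8 against 5.11 CPM), the RNA of the reporter's locus, Gt(ROSA)26Sor, (71.03 against 5.41 CPM) and Gria2 (104.7 against 8.52 CPM). Lower at E13.5 were the retinoid genes Stra6 (1.93 against 96.9 CPM) and Crabp2 (4.77 against 104.96 CPM), Cwc22 (16.7 against 316.02 CPM), Pde2a (8.30 against 132.3 CPM) and Ckb (11.7 against 101.6 CPM).

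Sympathoblast-like cells (cluster 5, then 3, 5 and 8) had no list with a median log2 fold between the ages of 1 or more in either direction. No G1S or G2M gene passed a 2-fold difference (medians -0.33 and -0.41), and neuronal and postsynaptic genes had medians of 0.30 and 0.40. The G1S, G2M, neuronal, postsynaptic, sympathoadrenal and stress medians lay beyond the percentiles 1 and 99 of random lists. The G2M median was -1.42 with a median over cells, -0.92 among female and 0.0380 among male cells. Ccser1 (51.1 against 6.42 CPM), Rabl2 (66.9 against 15.2 CPM), Slc6a2 (154.7 against 42.5 CPM), Cep250 (78.7 against 21.9 CPM) and Pik3cd (56.9 against 16.8 CPM) were higher at E13.5. Cwc22 (20.7 against 214.5 CPM), Unc5c (15.04 against 86.1 CPM), Chgb (91.5 against 320.8 CPM), Lrrn3 (78.7 against 250.97 CPM) and Itga1 (44.1 against 130.1 CPM) were lower.

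Bridge-like cells (clusters 4, 6 and 8, then 7) had less of the chromaffin and more of the glial transcripts at E13.5 under the grouping used for the other results. Catecholamine genes were at least 2-fold lower in 7 of 10 (median -1.98), such as Slc18a2 (0.856 against 54.02 CPM) and Dbh (58.7 against 354.6 CPM), and chromaffin markers in 6 of 6 (-2.37). Glial factors were higher in 8 of 12 (1.09), Schwann lineage genes in 8 of 16 (1.06) and matrix genes in 11 of 16 (1.19). Mesenchyme markers were higher too in summed reads, in 6 of 7 (2.14). Cells with at least 3 of these markers were not more common, at 13.54% of bridge-like cells at E12.5 and 12% at E13.5. G2M genes were lower in 11 of 20 (-1.03), where the E12.5 class included cluster 8 with mitosis genes in front. Stress genes were higher in 5 of 9 (1.10). Gas7 (172.1 against 16.5 CPM), Mmp2 (199.2 against 29.5 CPM), Ngfr (110.1 against 17.5 CPM), Ednrb (379.2 against 64.4 CPM) and Pik3r1 (344.6 against 60.1 CPM) were higher. Slc18a2, Eya1 (7.36 against 101.6 CPM), Agtr2 (147.6 against 1259 CPM), Cwc22 (40.8 against 313.7 CPM) and Cxadr (9.93 against 72.96 CPM) were lower. The level of Agtr2 at E12.5 came from a part of the cells, as the medians over cells were 28.6 CPM at E12.5 and 8.30 CPM at E13.5. These list differences depended on which cells were counted as bridge-like. With classes from the unlisted genes left out of the grouping the medians were 0.22 for catecholamine genes, -0.76 for glial factors, -0.20 for Schwann lineage and -0.60 for matrix genes. Without the 5% of wells with most genes they were -0.09, -0.07 and -0.19 for the last 3.

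Markers of other cell types were examined in every class, since the sort could let other cells through. The mesenchyme gene Postn was highest in SCP-like cells, at 2866 and 3019 CPM at E12.5 and E13.5, and was read in 100% of these cells. At least 3 mesenchyme markers were read in 88% and 78.5% of SCP-like and in 13.54% and 12% of bridge-like cells. At E13.5 Col1a1 (299.02 against 5.11 CPM) and Pdgfra (57.5 against 2.38 CPM) were higher in bridge-like than in SCP-like cells, and Col3a1 was lower (259.8 against 412 CPM). The highest endothelial marker was Egfl7 (30.1 CPM in E13.5 chromaffin-like cells) and the highest erythroid marker Hbb-y (6.51 CPM in E12.5 chromaffin-like cells). For the adrenal cortex it was Star (21.1 CPM in E12.5 sympathoblast-like cells), for immune cells Cd68 (11.6 CPM in E12.5 SCP/bridge cells) and for sensory neurons Ntrk2 (8.91 CPM in E13.5 bridge-like cells).

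A 2-fold difference was used as a rule of size, not as a test. Of the 90 programme list medians between classes of at least 1 in either direction, 87 lay at or beyond the percentiles 1 and 99 of 10000 random lists of like expression, as did all 9 such medians between ages. The other 3 were those of mature myelin genes at E13.5 in bridge-like (percentile 2.99) and chromaffin-like (2.48) over SCP-like cells and of Notch genes at E13.5 in sympathoblast-like over chromaffin-like cells (2.74). Percentiles describe these libraries only. The medians counted here were chosen for their size, and random lists took genes singly, so extreme percentiles follow in part from that choice. They do not show that a median is stable. In simulated data, 2.14 to 9.48% of the genes without a true difference passed 2-fold by counting and cell sampling alone, and 92.5 to 100% of true 4-fold differences did. These data used the spread between E12.5 chromaffin-like cells for every class, so the first percentages can be too low for more mixed classes. Medians within 1 of 0 are given as values only, since the sign of 23 of 48 such medians between classes and 39 of 60 between ages turned under at least 1 other way of processing. Larger medians turned too, in 2 of 90 between classes and 4 of 9 between ages. Those 4 were the catecholamine, glial factor, Schwann lineage and matrix medians of bridge-like cells.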

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

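All tests described here except that of the depth of the plates were chosen only after their results were seen, although the split by plate rows had been planned as an alternative, and the thinning behind the depth test was added after other results but before its own. Differences between the ages were not tested, since each age was 1 sample.

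In 14 comparisons of a listed gene between classes, the direction at E13.5 was opposite to that at E12.5, by at least 2-fold each time. In bridge-like over SCP-like cells the log2 folds at E13.5 were -2.52 for the transporter Slc18a2 (1.63 at E12.5), -3.19 for Rgs4 (3.68), -1.05 for Aurka (3.33), -2.51 for Aurkb (1.29), 1.54 for Cdkn1a (-2.01) and 2.29 for Egr1 (-3.05). In chromaffin-like over SCP-like cells they were -2.48 for Hey2 (2.56), -1.22 for Slc2a1 (1.75), 2.48 for Cdkn1a (-1.51) and -1.38 for Ier3 (1.28). In chromaffin-like over bridge-like cells they were 2.07 for Pcsk2 (-1.81) and -1.39 for Slc2a1 (1.49), and in sympathoblast-like over chromaffin-like cells -1.99 for Scg2 (1.44) and -1.65 for Vgf (1.11).

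Wells outside the comparisons also held reads. At E13.5, 8 wells had at most 736 reads (median 558, or 0.215% of the median well). Across 1000 genes, which are not independent of each other, the summed profile of these wells had a Spearman's rho of 0.446 with that of the plate. Chgb had 15 reads in these wells (3374 CPM, against 5043 on the plate).

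Sox10 in bridge-like cells stood at 63.4 and 200.7 CPM at E12.5 and E13.5, between SCP-like (1001 and 1205 CPM) and chromaffin-like cells (25.9 and 12.9 CPM). An SCP and a chromaffin cell in 1 well would give more genes than a single cell, but bridge-like cells had a median of 6782 genes at E12.5 after thinning, below the lower quartile of 8416 of 500 simulated mixes, and 6345 against 7849 at E13.5. Mixed pairs would also join male and female cells in 50% of wells at E12.5, while 0 of 99 bridge-like wells held both signals, with an upper 95% bound of 3.66% (0 of 25, a bound of 13.7% and 41.8% of mixes at E13.5). Stray reads would give sympathoblast-like cells the same share of cells with Sox10, but at least 2 reads of 100000 were found in 47.9% (37.6 to 58.4) of bridge-like against 6.06% (0.743 to 20.2) of sympathoblast-like cells at E12.5 and in 48% (27.8 to 68.7) against 5.17% (1.92 to 10.9) at E13.5, where reads at the rate of the nearly empty wells would add 0.621 CPM. These values count against stray reads as the whole source. Pairs of an SCP and a chromaffin cell could hardly be named bridge-like, so their outcome was largely set beforehand. Htr3a stood at 1.06 and 14.8 CPM in SCP-like and chromaffin-like cells, against 291.1 CPM in bridge-like cells at E12.5. A bridge-like cell in 1 well with an SCP was not simulated, and the check by sex supposes pairs from different embryos. A Sox10 level of single bridge-like cells remains a hypothesis, found and tested on the same data.

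Class shares differed between the ages, but with every well thinned the sympathoblast-like share was 32.6% at E13.5 against 9.21% at E12.5, and in rows A to H the SCP-like share was 19.02% against 4.76%, with intervals apart, which counts against depth and place on the plate as the whole source. Another mix of the sexes would leave the shares within each sex alike, but the bridge-like share of female cells was 5.96% at E13.5 against 21.5%, their sympathoblast-like share 54.3% against 11.2% and the SCP-like share of male cells 25.3% against 4.62%, each with intervals apart. The intervals of the 2 ages overlapped for the sympathoblast-like share of male cells (8.46% and 14.4%) and the SCP-like share of female cells (11.2% and 17.2%). With the SCP/bridge group counted in, the SCP-like share was 20.5% at E12.5 against 21.8%, with intervals that overlapped in 11 of 15 ways of choosing wells or grouping cells and were apart in the 4 that had no such group at E12.5, so a difference in SCP-like cells cannot be told apart from the naming of that group. By marker scores the group stood nearer to the bridge-like (0.859) than to the SCP-like class (0.735). For the sympathoblast-like share, 54.3% of female against 14.4% of male cells at E13.5 is consistent with embryos that gave unlike parts of the tissue, such as more of a ganglion, to the plate, while a difference between the sexes, age, litter and plate stay open.

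Cwc22, a splicing factor gene, was 6.92, 7.70, 18.9 and 10.4 times higher at E12.5 in SCP-like, bridge-like, chromaffin-like and sympathoblast-like cells. If only a few cells carried the reads, most cells would have none, but 100% of E12.5 cells of each class had a read. At E13.5 the share was 44.2 to 76% over the classes. These shares count against a few cells as the only carriers. A read in each cell does not show how evenly the reads were spread, so a few cells as the source of most reads was not excluded. A variant carried by the E12.5 litter may differ between embryos, and male cells stood at 1.70, 1.45, 1.55 and 1.50 times the level of female cells of the same class at E12.5, between the values set for and against this source. At E13.5, without the high level, the ratios were 0.492, 1.42, 1.80 and 0.640, so that ratios of this size cannot decide, and age and plate stay open as well. Cep250, higher at E13.5, and Acp1, higher at E12.5, were the only other genes that differed by at least 2-fold in all 4 classes with at least 20 CPM at the higher age in each class, with smallest folds of 2.33 and 2.24.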

How the results depend on the processing

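Of the alternatives reported here, those that thinned each well to 100000 reads, kept cells of 1 sex, counted SCP/bridge cells as SCP-like, left out the genes that name the classes, left Rn45s out of the totals, or took the list results from both ages clustered together were chosen after seeing the data, and the others before. No paired analysis was possible because each age was 1 sample and the numbers of the wells only name places on a plate. Depth limits the smallest classes most, with 25 SCP-like cells at E12.5 and 25 bridge-like cells at E13.5. Where no cause is named, the cause was not tested.

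Of the values of class shares under alternatives, 88 stayed within the 95% interval of the reported value and 54 did not. With SCP/bridge cells counted as SCP-like, the SCP-like share was 20.5% at E12.5, against 21.8% at E13.5 with overlapping intervals. The direction of the difference between ages was the same under all 15 ways for SCP-like, bridge-like and sympathoblast-like cells and for bridge-like cells with both boundary groups, and turned for chromaffin-like cells. Each way that changed the grouping gave a higher chromaffin-like share at E13.5, against the lower share of the reported grouping. At resolution 0.5 no cluster was SCP-like at E12.5 (0%, upper bound 0.966%), as its construction joins small clusters. The shares were then 36.8% for bridge-like, 16.8% for chromaffin-like and 73.7% for bridge-like cells with both boundary groups at E12.5 and 21.8% for bridge-like cells at E13.5. At resolution 2 they were 44.2% for bridge-like cells at E12.5 and, at E13.5, 13.7% for bridge-like cells, alone and with boundary groups, and 32.1% for chromaffin-like cells. Another seed gave 16.8% for chromaffin-like cells and 67.1% for bridge-like cells with boundary groups at E12.5, and at E13.5 13.48% for bridge-like cells, alone and with boundary groups, and 32.3% for chromaffin-like cells. The unlisted genes left out of the grouping gave 41.3% for bridge-like cells at E12.5, and at E13.5 12.1% for bridge-like cells, alone and with boundary groups, and 32.9% for chromaffin-like cells. Clustering on all expressed genes gave 12.9% for bridge-like cells, alone and with boundary groups, and 32.1% for chromaffin-like cells at E13.5. Both ages clustered together gave 42.1% for bridge-like, 31.1% for chromaffin-like and 51.8% for bridge-like cells with boundary groups at E12.5, and 12.7%, 32.1% and 14.6% at E13.5. The stricter limit on genes per well gave 43.5%, 16.9% and 66.2% at E12.5 in the same order. Without the 5% of wells with most genes the shares were 48.8%, 18.3% and 66.5% at E12.5, and 36.1% for chromaffin-like and 9.38% for bridge-like cells with boundary groups at E13.5. Wells thinned to 100000 reads gave 42.01% for bridge-like cells at E12.5, and at E13.5 13.8% for bridge-like cells, alone and with boundary groups, and 32.04% for chromaffin-like cells. Rows A to H and I to P of the plates gave 31.2% and 20.9% for bridge-like cells at E12.5 and 27.7% and 17.6% for bridge-like cells with boundary groups at E13.5. Wells with Xist reads, a subset by construction, gave 11.2% for SCP-like, 21.5% for bridge-like and 16.8% for chromaffin-like cells at E12.5, and at E13.5 17.2% for SCP-like, 12.6% for chromaffin-like, 54.3% for sympathoblast-like and 15.9% for bridge-like cells with boundary groups. Wells with Y-linked reads gave 32.5% for chromaffin-like, 14.4% for sympathoblast-like and 27.8% for bridge-like cells with boundary groups at E13.5.

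Of 2337 list medians between classes, 2212 stayed within the interval of the reported median and the others lay outside it. Among these, 2 that were reported at 1 or more in either direction had the opposite sign. Of 1161 medians between ages, 1091 stayed, 63 lay outside and 7 that were reported at 1 or more in either direction had the opposite sign. Scaling by TMM, means over cells, leaving out Rn45s, no limit on levels and leaving out the genes that name the classes moved none of them outside. Medians still changed within these intervals. Without the naming genes, the Schwann lineage median of chromaffin-like over SCP-like cells at E12.5 went from -4.91 to -3.08. The Notch median of the same comparison went from 0.39 to -0.82. With the median over cells of CPM, under which a gene read in fewer than 50% of cells counts as 0 by construction, the growth factor receptor median of chromaffin-like over bridge-like cells at E12.5 was 0.31 and the Notch median of sympathoblast-like over chromaffin-like cells at E13.5 was 0.13, both reversed. The same setting gave -5.91 for Schwann lineage genes in bridge-like over SCP-like cells at E13.5, -6.70 (E12.5) and -7.60 (E13.5) for them in chromaffin-like over SCP-like cells, 10.15 and 8.87 for catecholamine genes in chromaffin-like over SCP-like and over bridge-like cells at E13.5, -6.85 for G2M genes in chromaffin-like over bridge-like cells at E12.5, 6.95 for them in sympathoblast-like over chromaffin-like cells at E12.5, and -1.42 for them between ages in sympathoblast-like cells. The pseudocount sets the size of folds by construction. With 0.1 the medians were -6.99 for Schwann lineage genes in chromaffin-like over SCP-like cells at E13.5 and -5.57 (E12.5) and -4.91 (E13.5) for G2M genes in chromaffin-like over bridge-like cells. With 10 they were -3.80, -3.60 and -2.74 in the same order, and 4.01 (E12.5) and 3.64 (E13.5) for G2M genes in sympathoblast-like over chromaffin-like cells.

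The unlisted genes left out of the grouping turned the medians of bridge-like cells between ages to 0.22 for catecholamine genes, -0.76 for glial factors, -0.20 for Schwann lineage genes and -0.60 for matrix genes. It also gave -1.56 for Schwann lineage genes in bridge-like over SCP-like cells at E12.5 and -3.43 for G2M genes in chromaffin-like over bridge-like cells at E13.5. Without the 5% of wells with most genes, the medians of bridge-like cells between ages turned to -0.0888 for glial factors, -0.0688 for Schwann lineage genes and -0.19 for matrix genes, and the G2M median of chromaffin-like over bridge-like cells at E12.5 was -4.39. The stricter limit on genes per well gave -1.50 for Schwann lineage genes in bridge-like over SCP-like cells at E12.5, and both ages clustered together -3.72 for them at E13.5. G2M genes in chromaffin-like over bridge-like cells stood at -4.29 (E12.5) and -3.32 (E13.5) with both ages together, at -3.81 in rows A to H and -4.89 in rows I to P at E13.5, at -6.19 in wells with Xist reads at E12.5 and at -3.05 in wells with Y-linked reads at E13.5. In sympathoblast-like over chromaffin-like cells they stood at 6.75 in wells with Xist reads at E12.5. Between ages in sympathoblast-like cells they stood at -0.60 in rows A to H, 0.0380 in wells with Y-linked reads and -0.92 in wells with Xist reads, and catecholamine genes in bridge-like cells stood at -2.87 in wells with Xist reads.

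Of 53 shares of cells with mitosis transcripts, 20 moved outside the reported interval, 9 with each of the other limits on genes, which set the share by construction, and 2 without thinning. With 3 of 20 genes the shares were 92% of SCP-like, 90.6% of bridge-like and 43.6% of chromaffin-like cells at E12.5 and 77.2% of SCP-like, 24.7% of chromaffin-like and 94.8% of sympathoblast-like cells at E13.5. With 8 genes they were 48%, 58.3% and 1.06% at E12.5 and 35.4%, 1.18% and 76.7% at E13.5 in the same order. Without thinning, chromaffin-like cells stood at 17.5% and 13.95%. Of 42 shares of cells with Sox10 and Th, 10 moved. With 10 reads of each they were 0% of SCP-like and of bridge-like and 10.6% of chromaffin-like cells at E12.5, and 5.88% of chromaffin-like and 0.862% of sympathoblast-like cells at E13.5. No interval of chromaffin-like or bridge/chromaffin cells then lay above that of sympathoblast-like cells, which ends the separation found with 2 reads at E12.5 for the former and at E13.5 for the latter. With 1 read they were 22.8% of SCP-like cells at E13.5.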

Other observations

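SCP/bridge cells at E12.5 had Sox10 at 638 CPM, below SCP-like cells, together with Dll3 at 147.9 and Htr3a at 137.4 CPM, while Chga stood at 5.88 and Th at 8.01 CPM. Mki67 stood at 375.04 CPM in this group, and 86.8% of its cells (74.7 to 94.5) had at least 5 of the 20 G2M genes. Bridge/chromaffin cells had Htr3a at 38.3 and 64.5 CPM, Chga at 827 and 2073 CPM, Th at 589.7 and 684 CPM and Mki67 at 37.1 and 25.7 CPM at E12.5 and E13.5. The hypoxia factor gene Epas1 stood at 442 and 519 CPM and Cdkn1c at 5197 and 3028 CPM in them. These genes were picked after their values were seen, and no order in time was read from them. Several other groupings formed no bridge/chromaffin group at E13.5.

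Reads on genes at the same well position correlated between the plates (Pearson's r 0.705, Spearman's rho 0.708, 384 positions, two-sided permutation p 1e-05 each, the smallest that 100000 permutations can give). Without the 2 positions farthest from the median, r was 0.689, and over the 370 positions kept as cells on both plates r was 0.818 and rho 0.727. No other relation across wells was computed.

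No gene of the adrenal cortex list other than Star reached 5 CPM in any class or boundary group, and Nr5a1, the factor of steroid-making cells, had 0 reads in several of them. The melanocyte gene Tyr had 0 reads in E13.5 SCP-like cells, which allows up to 0.149 CPM, beside Pmel at 172.1 and Mitf at 7.43 CPM.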
